A study of Mus musculus with 18 samples.

How the data were processed

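Total RNA of mouse distal colon was measured on Affymetrix whole-genome expression arrays at 6 collection times, with 3 arrays per time. The deposited values are 1 table with a signal per probe set and array, made by the authors with GCOS, the Affymetrix array software named in the submitters' processing notes without a version. The deposited signal is on a linear scale, and the mean after removal of the lowest and highest 2% of probe sets was 500 in each of the 18 arrays, so each array carried 1 scaling factor. No pair of columns held identical values. The table gives no detection calls and no background level per probe set, so the number of arrays limits the precision, and the depth of a single signal is unknown.

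Of 45101 probe sets, 64 Affymetrix controls were set apart and used only for array quality. Among the 45037 left, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were not listed, and only the first kind was used for genes. Values were taken as log2(signal + 16), and the deposited scaling was kept because the array medians deviated from their median by at most 0.50 on the log2 scale, with a limit of 0.5 set for the change to quantile normalization (0.4966 before rounding, in 4am a). Probe sets were kept when their mean log2 over all arrays reached the 40th percentile (7.10), which left 27022. The probe set with the highest mean stood for each gene, giving 12870 genes. Gene positions come from the annotation of mouse genome build GRCm38.p6.

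Samples were grouped by the collection time in their titles, and hours after lights on were taken as the clock hour minus 7. A cosine curve with a period of 24 h was fitted per gene with limma 3.58.1 in R 4.3.3, which gave an amplitude on the log2 scale, a peak time and a moderated F statistic with 15 residual degrees of freedom before moderation. A second limma fit of 6 group means, with 12 residual degrees of freedom, gave the test of any difference between times and 4 contrasts: the mean of the 3 times in the light minus the mean of the 3 times in the dark, and 3 contrasts of times 12 h apart. Both fits used all 18 arrays and empirical Bayes moderation with a trend on the mean level. Adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05, and all tests are two-sided unless named otherwise. The moderated statistics pool the spread over genes, which lets adjusted p values be given for 3 arrays per time.

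Of 38 gene lists fixed beforehand, 35 had at least 3 members among the genes tested. The share of rhythmic genes in a list was compared with that in all other genes by a one-sided Fisher exact test. Each contrast was tested with camera from limma at a preset inter-gene correlation of 0.01, which compares the list with all other genes, and again with an estimated correlation, both adjusted over the lists of that contrast. Counts adjusted over the list alone are given for single members. As a test chosen after the data had been seen, the mean over the members of each list was fitted with the same cosine curve, with a permutation test of 100000 shuffles of the 18 arrays. An exact permutation test of the 8000 relabelings of arrays within the 3 sets of times 12 h apart went with it. Array quality was read from the ratio of 3′ to 5′ signal of the Gapdh and Actb controls and of phe, lys and thr, bacterial controls spiked into the RNA. A further one, dap, was not used since its median signal over the arrays was under 100.

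The genes named were set by a rule: every tested member of the lists core clock and clock outputs, up to 4 rhythmic genes with the largest amplitude per 4 h window of peak time, up to 10 genes per direction and contrast with the largest log2 difference among those past the threshold, and 2 to 4 members with the lowest adjusted p of each other list described. Clone names were counted and not named. The gene lists, tests, this rule and the alternatives not marked otherwise were chosen before the data were examined.

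The tests were tried on simulated data built from the residual spread of the 12870 genes, with planted effects. The cosine fit called 41.8% of genes planted at a log2 amplitude of 0.5, 94.0% at 1 and 98.5% at 2. A contrast of 3 against 3 arrays called between 0% and 1.49% of planted log2 differences of 0.5, between 26.9% and 38.8% of differences of 1 and between 77.3% and 80.3% of differences of 2. Light against dark called 23.9%, 88.1% and 97.0% of the same sizes. These shares hold for the simulated noise and may be too high for the real arrays. Among clock transcripts with a fitted amplitude above 1, Dbp (2.16), Tef (1.18) and Cry1 (1.05) passed in the real cosine fit. Nr1d1 (1.45), Ciart (1.11) and Per1 (1.05) did not, with limma adjusted p of 0.0594, 0.2997 and 0.9479.

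Alternatives changed the constant added before the logarithm, the normalization, the filter, the probe set per gene, the moderation, the curve fitted and the arrays used, with each array left out in turn. Letters a to c of the arrays were tried as a block. The deviations of arrays from their time's mean had a mean r of -0.0124 over the 45 pairs with the same letter and of 0.00608 over the 90 pairs with different letters, and 4 of 18 arrays had their best match at another time in an array with their own letter, so the letters were not used to pair arrays. Fits without the 3 arrays with the highest 3′ to 5′ ratios, with array quality weights, with the Gapdh ratio as a covariate and within sets of times 12 h apart, and the tests of lists with each array left out, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.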

Results

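The series asked which transcripts of the mouse distal colon are rhythmic over the day. Colon from just above the anus was taken every 4 h from mice adapted for 2 weeks to 12 h of light and 12 h of dark with free access to food, with lights on at clock hour 7 and off at 19. The 6 collection times, 8am, 12pm, 4pm, 8pm, 12am and 4am, fell 1, 5, 9, 13, 17 and 21 h after lights on, and each had 3 arrays, a to c. The labels do not say whether the arrays of a time came from separate mice or from pools, so the p values measure the spread between these samples.

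Median signals per array, over all probe sets, were 160, 183 and 165 at 8am, 202, 187 and 220 at 12pm, 197, 158 and 209 at 4pm, 178, 184 and 168 at 8pm, 213, 222 and 251 at 12am, and 127, 157 and 201 at 4am. Arrays of the same time correlated with a mean r of 0.934 on the log2 scale and arrays of different times with 0.910. The ratio of 3′ to 5′ signal of the Gapdh control lay between 0.746 and 1.12 in 14 arrays but was 34.3 in 4pm b, 2.33 in 4pm c, 36.0 in 4am a and 18.2 in 4am b. The Actb ratio was 4.99, 1.80, 55.4 and 16.6 in the same 4 arrays and at most 1.29 in the other 14.

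Transcripts of the circadian clock cycled in the distal colon over 24 h. Dbp, a transcription factor driven directly by the clock, had the largest swing, with a log2 amplitude of 2.16 ± 0.19 (SE) or 19.8-fold between peak and trough (adjusted p = 1.683e-05). Its mean log2 signal went from 8.00 ± 1.07 (SD, n = 3) at 8am to 11.83 ± 0.32 at 4pm and 11.72 ± 0.94 at 8pm, with a fitted peak 10.8 h after lights on. Its relative Tef, of the same family of transcription factors, peaked at 11.5 h with an amplitude of 1.18 ± 0.17 (adjusted p = 0.0261). Nr1d2, a nuclear receptor that represses clock genes, peaked at 10.3 h with an amplitude of 0.97 ± 0.14 and the same adjusted p of 0.0261. Cry1, a repressor of the clock loop, peaked late in the dark at 19.3 h, with an amplitude of 1.05 ± 0.16 (adjusted p = 0.0367). The 5th and last rhythmic gene was Slc36a1, a proton-coupled amino acid transporter. It peaked at 9.52 h with an amplitude of 0.72 ± 0.11, 2.72-fold between peak and trough (adjusted p = 0.0261). For Dbp, Tef, Nr1d2 and Slc36a1 all 3 arrays at 4pm lay above all 3 at 4am, and for Cry1 all 3 lay below.

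**Figure D1:**
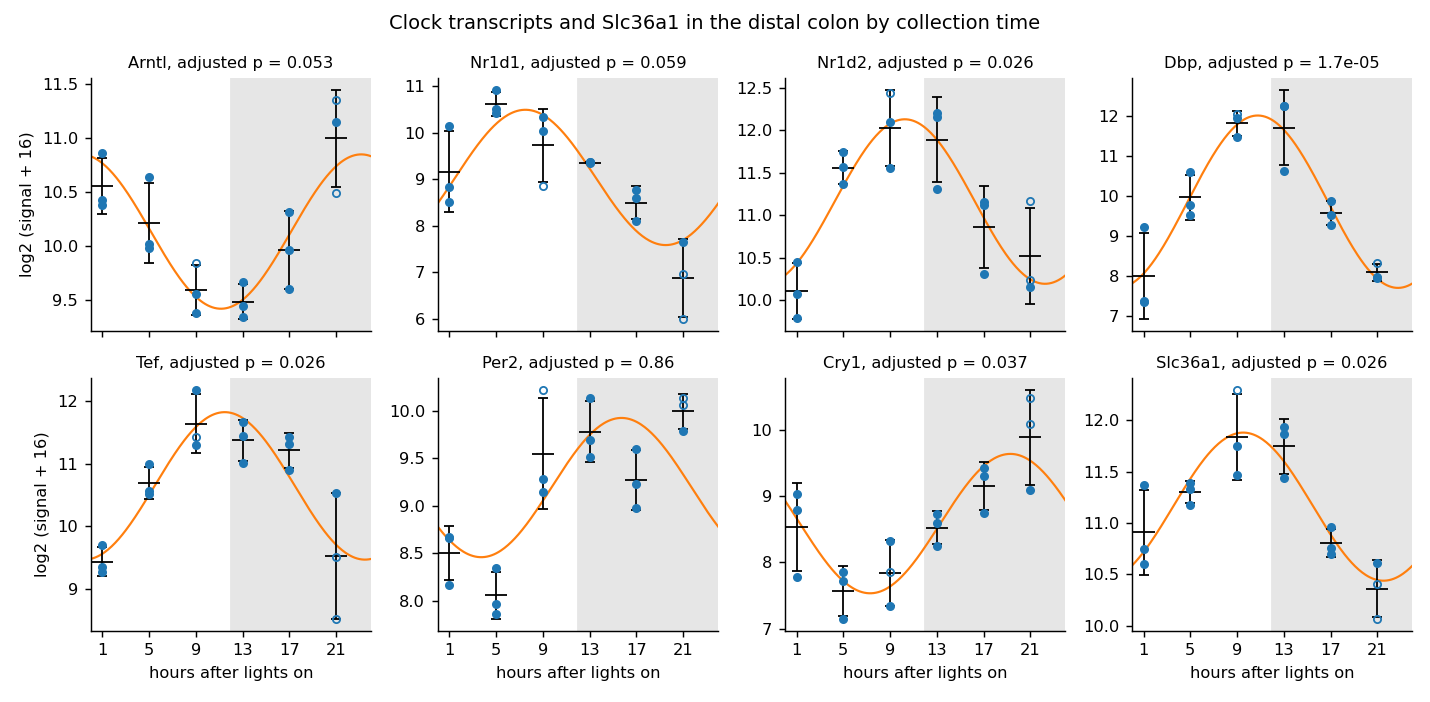
Log2 signal of 7 clock transcripts and Slc36a1 against hours after lights on, with 1 point per array, open points for 4am a, 4am b and 4pm b, black marks for the mean ± SD of the 3 arrays of a time, grey for the dark and an orange line for the fitted 24 h cosine curve. Dbp rose from a mean of 8.00 at 8am to 11.83 at 4pm, while Arntl was at 10.56 at 8am and at 9.59 at 4pm.

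In all, 5 of 12870 genes were rhythmic over 24 h, 4 with a peak in the light and 1 in the dark, and 509 had an unadjusted p under 0.05, where 643.5 would be expected without any rhythm. Differences between the 3 sets of times 12 h apart stay in the residual of this fit. A 12 h harmonic added to the curve, which here equals a block for these sets, gave 1100 genes at an unadjusted p under 0.05. Without 4am a, 4am b and 4pm b as well there were 1366, so the shortfall does not speak against further rhythmic genes. The core clock list held 2 of the 5 rhythmic genes among its 15 tested members (Fisher adjusted p = 0.0002214). Adjusted over the list alone 9 members passed. The clock outputs list also held 2, among 12 members (Fisher adjusted p = 0.0002214), with 7 adjusted over the list alone. The core clock lost its call without a filter (1 of 16, Fisher adjusted p = 0.0668) and with the replicate block (0 of 15, adjusted p = 1). Leaving out 1 array ended it for 13 of 18 arrays. It was kept without 8am c, 4pm c, 8pm c, 12am a or 12am c. The adjusted p was 0.0611 with 1 member without 4pm b or 4am a, and 1 with 0 members without any other array. Adjusted over the list alone 7 to 10 core clock members passed in these 18 fits. The clock outputs kept their call in all of them, with adjusted p of at most 0.0326. Other members passed adjusted over the list alone but not over all genes, with peaks spread along the day. Nr1d1, a relative of Nr1d2, had its fitted peak at 7.50 h (amplitude 1.45 ± 0.24, adjusted p = 0.0594), Per1 at 10.6 h, Per3 at 10.7 h, Ciart at 10.8 h and Per2 at 15.7 h. Arntl, the activator of the clock loop, stood opposite them at 23.1 h (amplitude 0.72 ± 0.12, adjusted p = 0.0532), with its partner Npas2 at 23.5 h. Per1 varied widely at 4am, at 7.18 ± 2.44 (SD, n = 3), and 1 of 3 arrays at 4pm lay above all 3 at 4am. The Per1 amplitude lay between 0.50 and 1.27 over the alternative limma fits. Of the outputs, Usp2 peaked at 13.6 h, Tspan4 at 13.6 h, Hlf at 13.8 h, Wee1, a kinase that holds back entry into mitosis, at 17.4 h, and Lonrf3 at 20.5 h. Clock, Cry2, Rora, Bhlhe40, Csnk1d and Csnk1e had amplitudes between 0.10 and 0.53 and did not pass adjusted over the list alone. Among the outputs, Dtx4, Coq10b, Nampt, Tsc22d3 and Cirbp did not pass, with amplitudes between 0.18 and 0.38.

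Dbp stayed past the threshold in 34 of 34 alternative limma fits with 1 value per gene, Tef in 25, Nr1d2 in 20, Slc36a1 in 18 and Cry1 in 14. The rank-based rhythm test, not among these 34, called no gene. Leaving out 1 array gave between 1 and 8 rhythmic genes, and without 4am a, 4am b and 4pm b there were 5, of which 3 were shared with the fit of all arrays. These 5 were Dbp, Nr1d1, Nr1d2, Tef and Cipc, so Cry1 and Slc36a1 lost their calls. With a 12 h harmonic as well, Slc36a1 passed (limma adjusted p = 0.0437) and Cry1 did not. The kept probe sets of a gene went the same way where there were several: the second set of Dbp peaked at 10.3 h and that of Tef at 10.8 h. When limma tested every probe set on its own, the second set of Dbp passed (adjusted p = 0.0001277) and that of Tef did not (0.9985). Nr1d2 and Slc36a1 then stood at 0.0516 and Cry1 at 0.0819.

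Mitotic transcripts were higher in the first hours of light. The mean over the 19 members of the mitosis list was 9.80 ± 0.36 (SD, n = 3) at 8am and 8.58 ± 0.08 at 8pm, and its 24 h curve had an amplitude of 0.45 ± 0.10 with a peak at 2.18 h (permutation adjusted p = 0.00747 over 35 lists). No member was rhythmic over all genes in limma, 12 had an unadjusted p under 0.05, and 11 passed adjusted over the list alone, with peaks between 0.64 and 4.41 h. They included the cyclin Ccnb2 (amplitude 0.71 ± 0.19), the spindle checkpoint kinases Bub1 (0.77 ± 0.19) and Bub1b (1.09 ± 0.27) and the kinase Aurka (0.59 ± 0.16). Without the 3 arrays with the highest Gapdh ratios the list amplitude was 0.49, with a peak at 1.18 h (permutation adjusted p = 0.00963). Shuffling arrays only within times 12 h apart gave an exact permutation adjusted p of 0.0866, which missed the threshold.

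**Figure D2:**
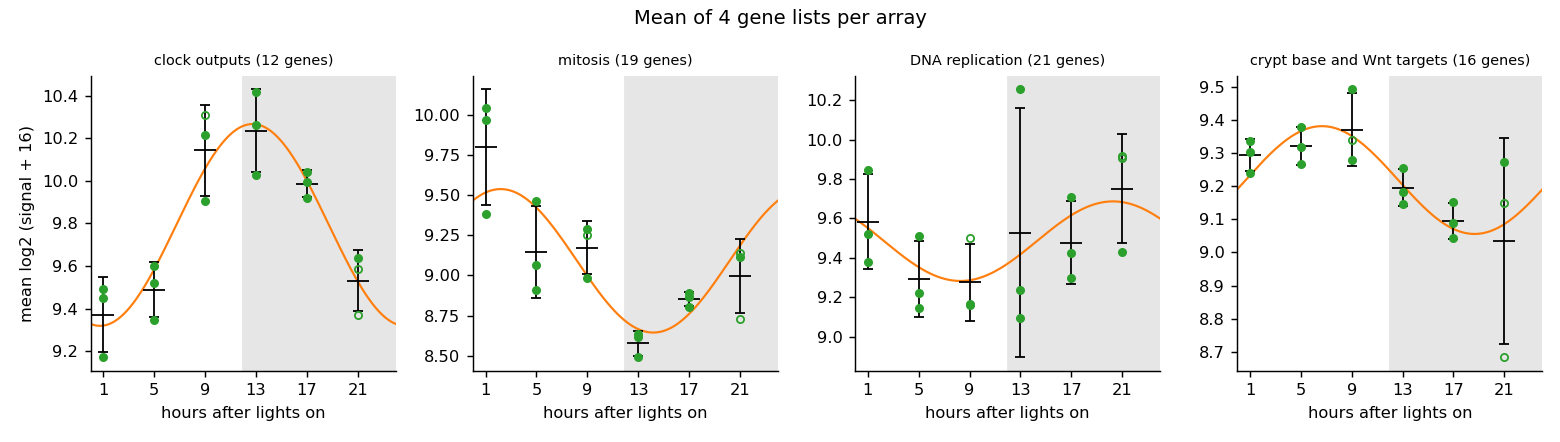
Mean log2 signal over the members of 4 gene lists against hours after lights on, with 1 point per array, open points for 4am a, 4am b and 4pm b, black marks for the mean ± SD of 3 arrays, grey for the dark and an orange line for the 24 h cosine curve. The mitosis mean was 9.80 at 8am and 8.58 at 8pm, and the clock outputs mean 9.37 and 10.23 at the same times.

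DNA replication transcripts showed no 24 h curve like that of the mitotic ones, but 1 array weighs on this. Their mean over 21 members had an amplitude of 0.20 ± 0.10 with a fitted peak at 20.3 h (permutation adjusted p = 0.425), and the difference between both lists changed over the day with an amplitude of 0.48 ± 0.15 (permutation p = 0.0137). The DNA replication mean was 9.58 ± 0.24 (SD, n = 3) at 8am and 9.53 ± 0.63 at 8pm, where 8pm c lay well above 8pm a and b. These curves were not fitted without 8pm c, so a fall from 8am to 8pm like that of mitosis is not excluded. The mean of the clock outputs had an amplitude of 0.47 ± 0.05 with a peak at 12.7 h (permutation adjusted p = 0.00105, and 0.00175 without the 3 arrays with the highest Gapdh ratios), and that of the core clock 0.22 ± 0.04 at 10.9 h (permutation adjusted p = 0.00747). Without the 3 arrays the core clock amplitude was 0.20 and missed the threshold (permutation adjusted p = 0.0743). Markers of the crypt base and targets of Wnt signalling, among them Rnf43, Ascl2 and Axin2, had a mean with an amplitude of 0.16 ± 0.04 and a peak at 6.66 h (permutation adjusted p = 0.0127, and 0.0347 without the 3 arrays), with 0 of 16 members rhythmic over all genes or adjusted over the list alone in limma and 2 at an unadjusted p under 0.05. In 2 other lists 1 member passed adjusted over the list alone. Cldn8, a tight junction protein, peaked at 0.01 h with an amplitude of 0.76 ± 0.16, and Ephx1, an epoxide hydrolase that detoxifies reactive compounds, peaked at 12.0 h with 0.52 ± 0.11.

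Any difference between the 6 times, whatever its shape, was found for 2183 genes, and 5439 had an unadjusted p under 0.05. They held 11 of 15 core clock members, 9 of 19 mitosis members and 7 of 12 clock outputs. Times 12 h apart went together in many genes. When 2 of the times were set against the other 4, 4pm and 4am together differed for 2365 genes, 8am and 8pm for 1481 and 12pm and 12am for 527, while the other 12 pairs of times gave between 0 and 3. With the 14 arrays of low Gapdh ratio, 8am and 8pm together gave 4011 genes, 12pm and 12am 1840, and 4pm and 4am, with 2 arrays left, 0. Tested within the 3 sets, from their 3 contrasts of times 12 h apart, 10 genes differed, all of them among the 2183. They were Dbp, Csrnp1, Nr1d1, Tef, Tspan4, Nr1d2, Ephx1, Slc36a1, Cry1 and 1 clone. These sets were chosen after seeing the data, and no label names a batch. Leaving out 4am c raised the count of 2183 to 6942. Without any 1 array of 8am, 8pm or 12am, or without 12pm a, 12pm b, 4pm a or 4am a, it fell to between 792 (without 8am c) and 1394 (without 4am a). Without 12pm c, 4pm b, 4pm c or 4am b it lay between 1468 and 2367.

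Light against dark asked which transcripts differ between the lit and the dark part of the day. No gene passed in limma (0 of 12870, 799 at an unadjusted p under 0.05), but mitotic transcripts as a group were higher in the light. Of the 19 mitosis members, 18 had a higher mean in the light, with a median log2 difference of 0.49 (camera adjusted p = 7.952e-15, and adjusted p = 0.0437 with an estimated correlation), and 12 rose adjusted over the list alone. The list mean of each of the 9 arrays in the light exceeded the median of the 9 in the dark. Bub1b was 3.33-fold higher (log2 difference 1.74 ± 0.32, SE), Plk1, a kinase needed to build the spindle, 2.07-fold and Ube2c, which marks mitotic proteins for breakdown, 1.97-fold, with adjusted p between 0.148 and 0.704 over all genes. Of the 3 pairs of times 12 h apart, the list had a median of 1.32 at 8am against 8pm, 0.29 at 12pm against 12am and 0.15 at 4pm against 4am. At 4pm against 4am 13 of 19 members were higher (camera adjusted p = 0.927) and none passed adjusted over the list alone.

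Clock outputs were lower in the light on average over the 3 pairs of times, with a median difference of -0.21 and 9 of 12 members lower (camera adjusted p = 0.000571, adjusted p = 0.0705 with an estimated correlation). The median was -0.37 without 4am b, and also without the 3 arrays with the highest Gapdh ratios. Adjusted over the list alone 5 fell, among them Wee1 (1.54-fold), Tspan4 (1.57-fold) and Hlf (1.37-fold). The sign was opposite at 4pm against 4am, where the list mean was 10.14 ± 0.21 (SD, n = 3) and 9.53 ± 0.14. There 3 of 3 arrays at 4pm lay above all of 4am, and the list mean peaked near lights off, at 12.7 h. B and plasma cell markers had a median difference of -0.41 with 12 of 12 lower (camera adjusted p = 8.474e-05, adjusted p = 0.231 with an estimated correlation). No member passed adjusted over the list alone, and Ms4a1, Fcmr and Ighm were 1.93-, 1.68- and 1.47-fold lower. DNA replication had a median of -0.29 with 16 of 21 members lower (camera adjusted p = 0.00117, adjusted p = 0.516 with an estimated correlation), including Ccne2 at -0.47 and Cdt1 at -0.43, and no member passed adjusted over the list alone. The highest list means were those of 8pm c (10.26, against 9.24 and 9.09 in 8pm a and b), 4am b (9.92) and 4am a (9.91, against 9.43 in 4am c). Without 8pm c the median was -0.18 and the call was lost (adjusted p = 0.177), and without the 3 arrays with the highest Gapdh ratios the median was -0.175 (adjusted p = 0.0362). MHC class II had a median of -0.15 with 8 of 9 lower (camera adjusted p = 0.0209, adjusted p = 0.516 with an estimated correlation), and H2-Aa alone fell adjusted over the list alone, by 0.52. This call was lost without 8am a (adjusted p = 0.0701), 12pm b (0.0808), 4pm b (0.121) or 4am c (0.2595), with medians of -0.10, -0.09, -0.10 and -0.08. Without 4am a or 4am b the median was -0.30 or -0.27. Crypt base markers had a median of 0.21 with 12 of 16 higher (camera adjusted p = 0.0492, adjusted p = 0.199 with an estimated correlation), with Smoc2 at 0.51, Axin2 at 0.45 and Lgr5 at 0.39. Endothelial markers had a median of 0.18 with 8 of 9 higher (camera adjusted p = 0.0492, adjusted p = 0.213 with an estimated correlation), led by Pecam1 at 0.80, and neither list had a member past the threshold adjusted over the list alone. The lowest endothelial means were those of 4am a (7.16) and 4am b (7.58), which have Gapdh ratios of 36.0 and 18.2, against 7.75 to 8.45 in the other 16 arrays. Without the 3 arrays with the highest Gapdh ratios the medians were 0.20 (adjusted p = 0.0114) and 0.15 (adjusted p = 0.0279). Leaving out 1 array lost the call of the crypt base list for 12 of 18 arrays, with adjusted p between 0.0522 (without 8am a) and 0.22 (without 4am c) and medians between 0.14 and 0.25. These were 8am a, b and c, 12pm a and b, 4pm a and b, 8pm c, 12am b and c and 4am a and c. It lost that of the endothelial list for 11, with adjusted p between 0.0506 (without 12am c) and 0.221 (without 4am c). These were 8am b and c, 12pm a and c, 4pm a and c, 8pm c, 12am b and c and 4am a and c. The endothelial median was 0.11 without 4am a, 0.30 without 4am c and between 0.13 and 0.25 in the other 9 of these fits, and 0.28 without 4pm b, where the call was kept. The calls of mitosis, clock outputs and B and plasma cells were kept without each of the 18 arrays. Leaving out 4am c alone brought 955 genes past the threshold in this contrast, and array quality weights 1942.

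At 8am against 8pm, 1 h after lights on against 1 h after lights off, mitotic transcripts were higher and clock outputs lower. All 19 mitosis members were higher at 8am, with a median log2 difference of 1.32 (camera adjusted p = 1.597e-46, and adjusted p = 0.000266 with an estimated correlation), and 18 passed adjusted over the list alone. Bub1 was 3.75-fold higher (1.91 ± 0.35), Ccna2 2.50-fold, Mki67, a marker of dividing cells, 2.54-fold and Birc5 2.66-fold, with no overlap between the 3 arrays of each time for the list mean. Tpx2, with a difference of 0.09 ± 0.34, was the member that did not pass. Dbp was lower at 8am by 3.72 ± 0.47 on the log2 scale or 13.2-fold (adjusted p = 0.00552), in 3 of 3 arrays. It was the 1 gene past the threshold over all genes, with 371 at an unadjusted p under 0.05. The clock outputs had a median of -0.45 with 10 of 12 lower (camera adjusted p = 2.809e-10, adjusted p = 0.0013 with an estimated correlation). Without 8am a the median was -0.23 (adjusted p = 9.995e-08). Tef, Hlf, Tspan4 and Usp2 were 3.82-, 2.01-, 2.66- and 2.29-fold lower at 8am and passed adjusted over the list alone.

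**Figure D3:**
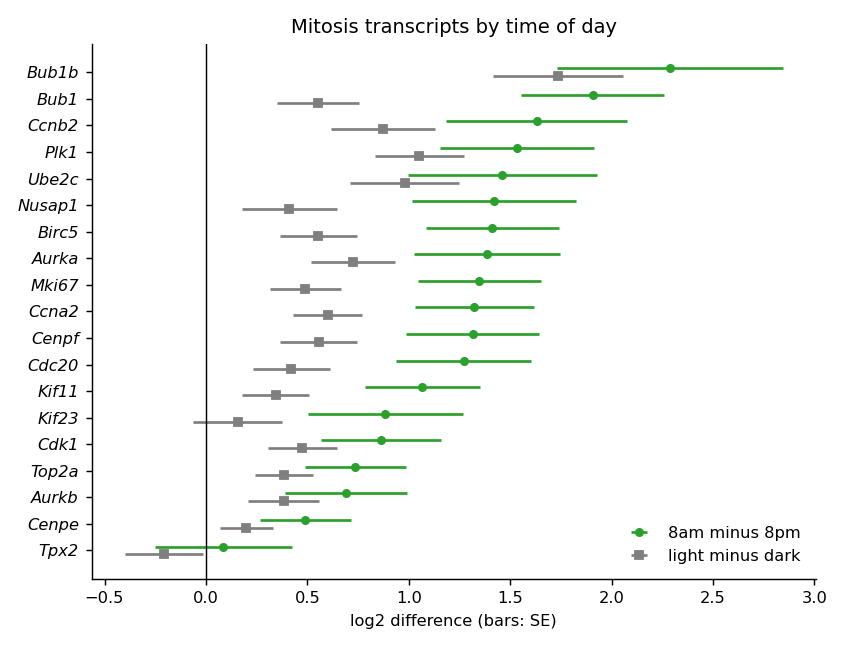
Log2 difference of the 19 mitosis transcripts between 8am and 8pm (green circles) and between light and dark (grey squares), with bars for the SE. All 19 lie above 0 at 8am against 8pm, and 18 of 19 do in light against dark.

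A further 6 lists were called at 8am against 8pm with the preset correlation and lost with an estimated one. Adipose markers had a median of -0.64 with 5 of 5 lower (camera adjusted p = 0.0014, adjusted p = 0.282 with an estimated correlation). Car3 and Adipoq were 4.44- and 4.37-fold lower at 8am and passed adjusted over the list alone. The mean of these markers was 8.41 ± 1.11 at 8am and 9.60 ± 0.55 at 8pm. B and plasma cell markers had a median of -0.55 with 11 of 12 lower (camera adjusted p = 0.0014, adjusted p = 0.282 with an estimated correlation), including Ighm at -0.76 and Blk at -0.60. MHC class II had a median of -0.41 with 9 of 9 lower (camera adjusted p = 0.00221, adjusted p = 0.33 with an estimated correlation), including H2-DMb2 at -1.41 and H2-Oa at -0.52. Cholesterol synthesis had a median of -0.33 with 15 of 18 lower (camera adjusted p = 0.00221, adjusted p = 0.33 with an estimated correlation), including Lss at -0.65 and Mvd at -0.70. Ion and water transport had a median of -0.17 with 20 of 28 lower (camera adjusted p = 0.0194, adjusted p = 0.0807 with an estimated correlation). Its Atp12a, the potassium-absorbing proton pump of the colon, was lower at 8am by 0.81 ± 0.19 and passed adjusted over the list alone. Sgk1, a kinase induced by corticosteroids, stood at -1.05 ± 0.36. Glucocorticoid response genes had a median of -0.19 with 14 of 16 lower (camera adjusted p = 0.0337, adjusted p = 0.282 with an estimated correlation), with Sgk1 shared with the transport list and Zbtb16 at -0.60. No member of the last list or of the B cell, MHC class II and cholesterol lists passed adjusted over the list alone. Each of these 6 calls was also lost by leaving out 1 array. Adipose markers and MHC class II lost theirs without 8am a (adjusted p = 0.115 and 0.116), with medians of -0.42 and -0.28, and B and plasma cells without 8am c (0.266), with -0.32. Without 8am b the median of cholesterol synthesis fell to -0.14 (0.317) and that of ion and water transport to -0.06 (0.36). Both calls were also lost with medians near those of all arrays, cholesterol synthesis without 8pm c (-0.29, adjusted p = 0.067) and ion and water transport without 8pm a (-0.15, adjusted p = 0.054). Glucocorticoid response lost its call without 8am a (0.181), 8pm a (0.162) or 8pm b (0.116), although its medians were -0.25, -0.19 and -0.17. In 3 fits a median moved by over 1.5 times and the call was kept, to -1.05 for adipose markers without 8am b, -0.11 for ion and water transport without 8pm b and -0.31 for glucocorticoid response without 8pm c. The call of Dbp, the single gene, was lost without 8am a, 8am b, 8pm a or 8pm b, where its log2 difference was still -3.40 or larger in size, with adjusted p between 0.0571 and 0.0814. The gene count was then 0. It was 18 without the 3 arrays with the highest Gapdh ratios and 24 when only the 6 arrays were fitted.

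Between 12pm and 12am no gene passed in limma (0 of 12870, 1044 at an unadjusted p under 0.05). The clock outputs were lower at 12pm, with a median of -0.55 and 10 of 12 members lower (camera adjusted p = 0.00404, adjusted p = 0.196 with an estimated correlation). Tspan4, a membrane protein of the tetraspanin family, was 3.45-fold lower at 12pm and Wee1 2.18-fold, each past the threshold adjusted over the list alone. Each was lower in 3 of 3 arrays than in any array of 12am. Nr1d1 stood at 2.13 and Cry1 at -1.58 in this contrast, where 4 of 15 core clock members passed adjusted over the list alone. The mitosis list had a median of 0.29 with 16 of 19 members higher (camera adjusted p = 0.0582), and no member passed. Without the 3 arrays with the highest Gapdh ratios 16 genes passed, although none of those arrays belongs to either time.

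Between 4pm and 4am 6 genes passed, all higher at 4pm, with 2533 at an unadjusted p under 0.05. Dbp was 13.3-fold higher (3.73 ± 0.47, adjusted p = 0.00263), Csrnp1, a nuclear protein, 4.17-fold (2.06 ± 0.26, adjusted p = 0.00263), and Nr1d1 7.29-fold (2.86 ± 0.45, adjusted p = 0.0196). Wnk4, a kinase that regulates ion transport, was 3.45-fold higher (1.79 ± 0.30) and Slc36a1 2.78-fold (1.48 ± 0.25), each with adjusted p = 0.0361, and the last was a clone. All 3 arrays at 4pm lay above all 3 at 4am for each of these 5 named genes. Csrnp1 stood apart at 4am, at 6.25 ± 0.13 against means between 8.22 and 8.57 at the other 5 times. In the core clock list 11 of 15 members passed adjusted over the list alone, 7 of them higher at 4pm. In the clock outputs 6 of 12 passed, with Dbp, Tef, Tspan4 and Dtx4 higher and Lonrf3 and Nampt lower at 4pm. DNA replication was the 1 list called, with a median of -0.46, or -0.58 relative to the median of all genes in this contrast (0.12), and 18 of 21 members lower at 4pm (camera adjusted p = 0.00046, adjusted p = 0.949 with an estimated correlation), including Pcna at -1.13, Pola1 at -1.03 and Prim1 at -0.99, and no member passed adjusted over the list alone. The call was kept without each single array, with a median of -0.72 without 4am c, and without the 3 arrays with the highest Gapdh ratios the median was -0.36 (adjusted p = 0.0461).

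The contrast of 4pm and 4am held the 3 arrays with Gapdh ratios of 34.3, 36.0 and 18.2, and without them, with 2 arrays at 4pm and 1 at 4am, 0 genes passed in limma and 799 had an unadjusted p under 0.05. In that fit the single array at 4am is assumed to vary like the others. The differences stayed at 3.72 ± 0.71 for Dbp, 2.12 ± 0.38 for Csrnp1, 2.52 ± 0.47 for Nr1d1 and 1.82 ± 0.37 for the clone (1.92 ± 0.27 with all arrays). Their adjusted p lay between 0.146 and 0.218, as the SE rose with fewer arrays. Wnk4 and Slc36a1 fell to 1.14 ± 0.36 and 0.99 ± 0.29. Without 4am c alone, the array of that time with a Gapdh ratio of 0.75, 4090 genes passed.

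**Figure D4:**
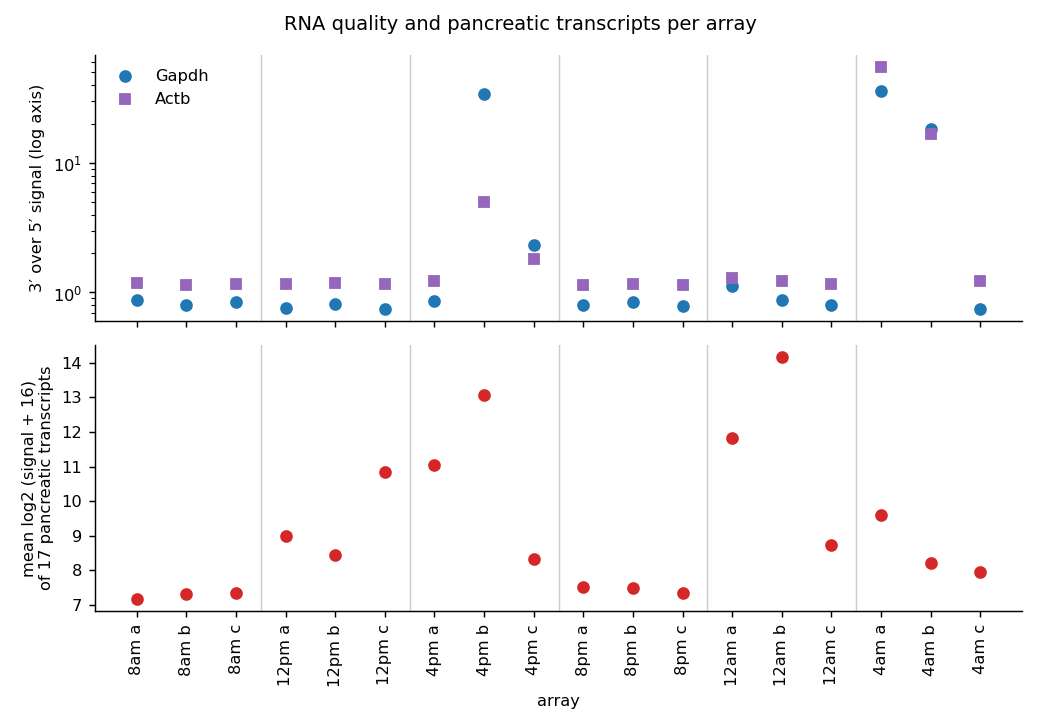
Upper panel: ratio of 3′ to 5′ signal of the Gapdh and Actb controls per array, on a log axis. Lower panel: mean log2 signal of 17 transcripts of the exocrine pancreas per array. The Gapdh ratio was above 18 in 4pm b, 4am a and 4am b, and the pancreatic mean was 14.2 in 12am b and 13.1 in 4pm b against 7.16 to 7.53 in the 6 arrays of 8am and 8pm.

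Of the 35 lists tested, 22 were called in no test, with a lowest camera adjusted p of 0.0556 and a lowest permutation adjusted p of 0.0674 for the 24 h curve of the list mean, and none of their members was rhythmic over all genes. They covered stress and nutrient programmes (immediate early genes, heat shock proteins, the unfolded protein response, the amino acid response, fatty acid synthesis, oxidative phosphorylation), defence and barrier genes (xenobiotic metabolism, tight junctions and adhesion, antimicrobial defence, the interferon response), markers of epithelial cells (goblet cells, enteroendocrine cells, surface colonocytes, squamous epithelium) and markers of the wall and immune cells (enteric neurons, enteric glia, smooth muscle, skeletal muscle, fibroblasts, T cells, macrophages) and sex chromosome markers. Blood, mast cell and male accessory gland lists had 1, 1 and 2 members above the filter and were not tested.

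The genes past a threshold lie, in mouse build GRCm38.p6, on chromosome 7 from 45705100 to 45710203 (Dbp), chromosome 15 from 81802673 to 81826863 (Tef), chromosome 14 from 18204056 to 18239106 (Nr1d2), chromosome 10 from 85131700 to 85185054 (Cry1) and chromosome 11 from 55204322 to 55236330 (Slc36a1). Nr1d1 lies on chromosome 11 from 98767932 to 98775377, Wnk4 on chromosome 11 from 101260537 to 101277409 and Csrnp1 on chromosome 9 from 119971163 to 119984742. Their Entrez gene numbers in the annotation are 13170 (Dbp), 21685 (Tef), 353187 (Nr1d2), 12952 (Cry1), 215335 (Slc36a1), 217166 (Nr1d1), 69847 (Wnk4) and 215418 (Csrnp1).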

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

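The arrays give no detection calls or background, so signal over background was not available, and 3 arrays per time with 3 of 18 of high Gapdh ratio limit what these counts can show. Fits with 3 arrays left out, array quality weights or the Gapdh covariate, fits without 4am, fits within the sets of times 12 h apart, list means, the replicate block for lists enriched in rhythmic genes, and 3 arrays or 1 left out for lists were chosen after seeing the data. Of the values of named genes and lists under the alternatives, 2946 kept their direction and side of the threshold, 95 moved past it, 163 fell short of it and 7 changed direction, none of them past the threshold. H2-Ab1 in light against dark went from -0.30 to 0.1993 with the mean over probe sets. The fitted peak moved by over 6 h for Csnk1d with that mean (amplitude 0.1531), 3 arrays left out (0.0893) or 4am left out (0.1264), for Dtx4 with 3 arrays left out (0.0703) and with a 12 h harmonic as well (0.0874), and for Nampt with 4am left out (0.0342). Counts of genes are given in the order rhythmic over 24 h, differing between times, light against dark, 8am against 8pm, 12pm against 12am and 4pm against 4am, where the values from all 18 arrays were 5, 2183, 0, 1, 0 and 6. A count not given stayed within 1.5 times its value, fits without 1 array included. Where no cause is named, the cause was not tested.

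Adding 1 instead of 16 before the logarithm gave 1 gene for 12pm against 12am, and adding 64 gave 8 rhythmic genes and 10 for 4pm against 4am. Quantile normalization gave 8 rhythmic genes, 1 for light against dark and 5 for 12pm against 12am, and centring the arrays on their median gave 1 for light against dark. Median centring moved the median over all genes from -0.03 to 0.13 for 12pm against 12am and from 0.12 to -0.09 for 4pm against 4am, and the 17 called lists kept the sign of their median under the 3 scalings. Without a filter 8am against 8pm had 2 genes and 1 list was enriched in rhythmic genes instead of 2. The mean over a gene's probe sets gave 2 genes for 12pm against 12am and 10 for 4pm against 4am. With every probe set on its own, so with more features tested, 3 were rhythmic, 3492 differed between times and 2 differed for 12pm against 12am. The replicate block gave 1 rhythmic gene and 1 enriched list. A rank-based rhythm test gave 0 genes, with 525 at an unadjusted p under 0.05 and a smallest p of 1.2872e-05, while limma gave 5 with 509. A Kruskal-Wallis test of the 6 times gave 0, with 3026 at an unadjusted p under 0.05. The smallest p this design can give is 0.005372, at which 1383 genes would be needed to pass, so this 0 says little. Fits of only the 6 arrays of a contrast gave 24, 1 and 1 genes for 8am against 8pm, 12pm against 12am and 4pm against 4am.

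Adding a 12 h harmonic to the curve, which here equals a block for the 3 sets of times 12 h apart, gave 11 rhythmic genes with all 5 from before, and 20 with 3 arrays left out as well, 4 of them shared. The 3 arrays left out alone gave 2 genes for light against dark, 18 for 8am against 8pm, 16 for 12pm against 12am and, with 2 arrays against 1, 0 for 4pm against 4am in limma with 799 at an unadjusted p under 0.05. All 4am arrays left out gave 3 rhythmic genes. The Gapdh covariate gave 9 rhythmic genes, 3 for light against dark, 5 for 12pm against 12am and 215 for 4pm against 4am. Array quality weights gave 29, 8974, 1942, 286, 432 and 3275. Differences between times within the 3 sets of times 12 h apart were found for 10 genes, and for 14 with 3 arrays left out. Of the 17 calls of gene lists over 4 contrasts, 3 held with an estimated correlation, those of mitosis in light against dark and of mitosis and clock outputs at 8am against 8pm. List means had a 24 h rhythm in 4 lists by permutation of all arrays and in 5 by exact permutation within the sets of times 12 h apart.

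Leaving out each of the 18 arrays in turn gave from 1 to 8 rhythmic genes: 1 without 8am a, 8am b, 12pm c, 4pm a, 8pm a, 8pm b or 4am b, 2 without 12pm a, 12am b or 4am c, 3 without 12pm b, 4pm b or 4am a, and 8 without 8pm c. Genes differing between times ran from 792 without 8am c to 6942 without 4am c, with 858 and 1344 without 8am a and b, 1159 and 1282 without 12pm a and b, 1381 without 4pm a, 919, 1065 and 992 without 8pm a, b and c, 1256, 1069 and 1035 without 12am a, b and c and 1394 without 4am a. The 6942 held all 2183 genes. Light against dark gave 955 without 4am c, 2 without 4pm b, 1 without 4pm c and 0 without any other array. The contrast of 8am against 8pm ran from 0 (without 8am a, 8am b, 8pm a or 8pm b) to 4 (without 4am a), with 3 without 4am c. For 12pm against 12am the range was 0 to 3, with 1 without 8am b, 4am a or 4am b and 3 without 4am c. For 4pm against 4am it was 2 (without 4am b) to 4090 (without 4am c), with 3 without 4pm a or 4am a. Calls of gene lists ran from 14 (without 8am a or 4am c) to 24 (without 4am a), and lists enriched in rhythmic genes from 1 to 2.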

Other observations

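The exact permutation test of list means within the sets of times 12 h apart, chosen after the data were seen, was passed by 2 lists that no other test of a 24 h rhythm called. Genes of fatty acid oxidation and ketogenesis had a mean with an amplitude of 0.11 ± 0.03 on the log2 scale and a peak at 8.77 h after lights on (exact permutation adjusted p = 0.0321), with 0 of 15 members rhythmic over all genes or adjusted over the list alone in limma and 1 at an unadjusted p under 0.05. Cpt1a, which brings fatty acids into mitochondria, stood at an amplitude of 0.25 ± 0.08. Ion and water transport had a mean with an amplitude of 0.12 ± 0.04 and a peak at 11.6 h (exact permutation adjusted p = 0.0321), with 0 of 28 members rhythmic and 5 at an unadjusted p under 0.05, among them the potassium channel Kcnq1 at 11.3 h, Atp12a at 13.5 h and Sgk1 at 14.5 h. By permutation of all 18 arrays both lists had an adjusted p of 0.0674, and without the 3 arrays with the highest Gapdh ratios 0.155 and 0.1415, so of these tests they passed only the one that held the sets of times apart. The clock outputs (0.00875), the core clock (0.0367) and the crypt base markers (0.0367) also passed the exact permutation test within the sets.

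Fits added after the data were seen named further clock transcripts, chosen here after their values were seen. With a 12 h harmonic and 3 arrays left out, Per2, Arntl, Usp2, Hlf and Cipc, a protein that binds Clock, joined Dbp, Tef, Nr1d1 and Nr1d2 among 20 rhythmic genes. The cell division genes Bub1b, Knl1 and Hmgb2 were also among them, with peaks at 1.96, 0.47 and 2.97 h and amplitudes of 1.05 ± 0.16, 0.52 ± 0.09 and 0.47 ± 0.08 (adjusted p = 0.0272, 0.0482 and 0.0482). With array quality weights Cldn8 peaked at 0.55 h (adjusted p = 0.0106) and Ephx1 at 12.7 h (adjusted p = 0.0205) among 29 rhythmic genes.

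The tests on 4pm a, 4pm c and 4am c, on the spiked controls, on the 3 sets of times 12 h apart, on a 12 h rhythm and on the pancreatic transcripts were chosen only after the result was seen. Those of the within-gene spread and of other groupings of the arrays were set before their results. The within-gene test named 4pm b, 4am a and 4am b and set 4pm c apart, so array quality was known by then. The first pattern is the low correlation of 4pm b, 4am a and 4am b with the other arrays. Probe sets of the same gene moved apart in these 3 arrays, with a median within-gene SD of at least 0.48 against at most 0.36 in the 14 arrays other than these and 4pm c (0.40 in 4pm c), so a loss of 5′ signal may account for it. Positions of the probe sets in the gene were not used, so another source of such spread is not told apart. With the 12 arrays of the other 4 times, 4pm a, 4pm c and 4am c had a mean r of at least 0.914, and 4pm b, 4am a and 4am b of at most 0.895. This order alone decides nothing, as the pattern was named from the low correlation of these 3 arrays. Collection time alone is argued against by 4pm a (0.938) and 4am c (0.934), which lay within the 0.915 to 0.941 of the 12 arrays. The value of 4pm c (0.914) lay just below that range. Damage to the tissue RNA alone is argued against in 4am a and 4am b, since bacterial controls spiked into the RNA also lost 5′ signal there. The geometric mean of the ratios of phe, lys and thr was 22.5 in 4am a and 7.85 in 4am b, against at most 4.80 in the 15 arrays outside the 3. That highest value was in 4pm c, whose Gapdh ratio was 2.33, and the other 14 had at most 1.74. Of the single ratios in 4am b, lys (4.86) and thr (21.1) exceeded those of 4pm c (2.56 and 6.12) and phe (4.71) did not (7.06). In 4pm b the geometric mean of 2.21 lay between both bounds, with phe (1.56) and lys (1.09) within the range of the 14 arrays and thr (6.32) above it, so damage to the tissue RNA alone stays open there. Whether time of death or dissection contributed was not tested.

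The second pattern is the likeness of times 12 h apart. Arrays of times 12 h apart correlated with a mean r of 0.930 against 0.905 for other different times, and with 0.946 against 0.927 among the 14 arrays. Control transcripts of the hybridization mix, which no mouse RNA holds, had a mean log2 signal of 11.45 ± 0.11 (SD, n = 6) in the 8am and 8pm arrays, 10.99 ± 0.22 in those of 12pm and 12am and 10.96 ± 0.53 in those of 4pm and 4am (exact permutation p = 0.0413 over 2858856 partitions). The controls set only the 8am and 8pm arrays apart, so separate handling could account for the likeness of these. Between the other sets the controls give no sign of separate handling. Their signals also carry the scaling factor of each array, so a shift in the tissue signals could move them. A 12 h component passed for 4208 genes, but the design has the same 3 pairs of times for a 12 h rhythm of the tissue and for handling in sets, so both cannot be told apart. Contrasts within a set are not shifted by a constant difference between the sets.

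The third pattern is pancreatic enzyme transcripts in single arrays, from a list of 17 genes chosen after the data were seen. Their mean log2 signal was 14.2 in 12am b, 13.1 in 4pm b, 11.8 in 12am a, above 10.8 in 4pm a and 12pm c and 9.60 in 4am a, against 7.16 to 7.53 in the 6 arrays of 8am and 8pm, and Prss2 reached a signal of 26906 and Clps 25821 in 12am b. Pancreatic RNA carried into single samples is a candidate explanation that stays open, since the median Spearman correlation of the genes was 0.689, just under the 0.7 set for it, and 2 of the 17, Sycn and Cela1, had a mean signal above 1000 in the 8am and 8pm arrays too. Collection time could also account for part, with 60% of the variance of the list mean between times (permutation p = 0.0388), although the 3 arrays at 12am ran from 8.74 to 14.2. All 6 arrays of 8am and 8pm lay below the arrays of the other times, which ran from 7.96 to 14.2. The permutation shuffled all arrays freely, so it cannot tell collection time from the sets of times 12 h apart. Of 12870 genes, 16 followed the list mean with r over 0.9, 12 of them on the list, and 6 of the 16 were among the 2183 genes that differed between times.

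Other groupings of the arrays were counted for each result. Among 100 groupings of the 18 arrays into 6 times of 3, the real one included, 1 gave as many rhythmic genes (5 in the real one, at most 2 in the others), 1 gave as many genes differing between times (2183, at most 1 in the others) and 1 gave as many lists enriched in rhythmic genes (2, and 0 in the others). Free shuffles of all arrays thus rarely reach these counts. They also break up the sets of times 12 h apart and the 4pm and 4am arrays of high Gapdh ratio. They therefore cannot tell time of day from these structures, and within the sets 10 genes differed. The list count adds little, as the shuffles had at most 2 rhythmic genes. For light against dark 100 of 100 gave as many genes (0, at most 1 in the others). With 0 genes in the real grouping this was bound to happen, so it decides nothing. As many called lists came from 21 of 100 (7, at most 14), so chance is not excluded for the lists. Each contrast of times 12 h apart has only 10 splits of its 6 arrays, too few for a share under 0.05. At 8am against 8pm 1 of 10 gave as many genes (1, and 0 in the others) and 6 of 10 as many lists (8, at most 16). At 12pm against 12am 10 of 10 gave as many genes (0, at most 1), again bound to happen, and 9 of 10 as many lists (1, at most 8). At 4pm against 4am 4 of 10 gave as many genes (6, at most 4531) and 8 of 10 as many lists (1, at most 7). The split with 4531 genes set 4pm a, 4pm c and 4am c against 4pm b, 4am a and 4am b, which follows the Gapdh ratio and points to a structure of the samples. Without these 3 arrays 0 genes passed in limma, with 799 at an unadjusted p under 0.05, while the differences of Dbp, Csrnp1 and Nr1d1 between 4pm and 4am were 3.72, 2.12 and 2.52 against 3.73, 2.06 and 2.86 with all arrays.

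A hypothesis from these data is that cells of the distal colon enter mitosis preferentially in the early light phase, with DNA replication not following the same course. The test, chosen only after the result was seen, was the difference between the mean of the mitosis and the DNA replication list, whose 24 h curve had an amplitude of 0.48 with a peak at 3.83 h (permutation p = 0.0137, and exact permutation p = 0.0428 within the sets of times 12 h apart). Without the 3 arrays with the highest Gapdh ratios the amplitude was 0.48 with a peak at 2.40 h (permutation p = 0.0109). The DNA replication mean at 8pm was 9.53 ± 0.63 (SD, n = 3), with 8pm c well above 8pm a and b. The difference was not fitted without 8pm c, so the part on DNA replication stays open. The hypothesis was found and tested on the same data, and the mitosis mean alone missed the threshold within the sets (exact permutation adjusted p = 0.0866).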
